A study of Homo sapiens with 9 samples.

How the data were processed

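The series measured gene expression by RNA sequencing in THP-1 cells, a human monocytic leukaemia line. Per the labels, all cells were first stimulated with PMA, a phorbol ester that makes this line adhere and take on macrophage features. They were then given PBS (control), LPS (lipopolysaccharide of the outer membrane of Gram-negative bacteria) or LPS with ABS. The labels do not spell out ABS, and the series title speaks of apoptotic bodies. Doses and times were not given in the sources used here. Each group had 3 libraries, 9 in all, and no label says that they came from separate cultures, so p-values measure the spread between these samples, which can be technical.

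Per the labels' protocols, total RNA was extracted with TRIzol, and 2 library kits are named for every sample, a TruSeq stranded mRNA kit and a VAHTS Universal V5 kit, without saying which was used. Per the submitters' processing notes, fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 were used, with no role or order given. The genome build, the annotation and the strand setting of the counting were not given in the sources used here, so genes that overlap or lie antisense to one another cannot be separated by strand with certainty. The authors deposited a table of raw read counts per gene and library and a table of FPKM values, both for 16222 genes. The deposited FPKM values equalled the count divided by 1 length per gene and by the library's total count. In all 16222 genes the length so implied varied between libraries by at most 1.1e-15 of its mean. No entry lacked a gene name.

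Total counts per library ranged from 38506162 to 41679412, and the genes tested held 99.985% of them. The spread between libraries beyond counting error, as a common coefficient of variation, was 18.4%. Counting error of a gene with 100 counts is 10%, so at this depth it limited mainly genes with fewer counts. Samples were grouped by the treatment in their labels, and columns were matched to samples by title. No pair of libraries of 1 group was a duplicate, since the lowest chi-square per degree of freedom within groups was 7.22.

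Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group (12970 genes) and scaled by TMM. A quasi-likelihood F test compared 3 group means fitted to all 9 libraries, with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 with their standard error (SE). Levels (CPM) are counts scaled to library size after TMM, as mean ± SD over 3 libraries.

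Gene lists were fixed before the data were examined, 31 in all. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, 24 lists in 1 Benjamini-Hochberg family per comparison. The 24 lists covered inflammatory cytokines and chemokines, NF-kB feedback regulators, type I interferon response, M1-type markers, M2-type markers, anti-inflammatory mediators, Toll-like receptor signalling components, apoptotic cell uptake, LXR targets and cholesterol efflux, cholesterol synthesis, lysosome and glycolysis. They also covered oxidative phosphorylation, NRF2 and oxidative stress, unfolded protein and integrated stress response, apoptosis and p53 targets, inflammasome and pyroptosis, cell cycle, matrix proteases, MHC class I and class II presentation, monocyte and macrophage identity, cytoplasmic ribosomal proteins and immediate early genes. Of the rest, 6 lists held markers of other cell types (fibroblast, chondrocyte, T cell, B cell, endothelial and epithelial) and were described by level, and the list of mitochondrially encoded mRNAs had 0 members among the genes tested. Counts of members changed are given over all genes tested and adjusted over the list alone. A list was also tested with an estimated correlation and with fry. With an estimated correlation camera called 0 lists in each comparison (3, 3 and 4 had an unadjusted p under 0.05), whereas fry called 7, 8 and 10.

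Genes were named by a rule fixed before the data were examined. In each comparison it took the 8 largest rises and the 8 largest falls among called genes whose groups of 3 libraries did not overlap, with at least 100 counts per library on average in the higher group. It added up to 4 members with the smallest adjusted p of each list described, and 18 landmark genes of macrophage activation. Of these 18, IL6, IL10 and CD86 had too few counts to be tested, and the deposited counts held no gene under the symbol MRC1.

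After the data were seen, a trend of the counts with GC content was found in the libraries, and a correction was added. For each library the log count, relative to the mean over libraries, was fitted by lowess (span 0.3) on the GC content of the longest protein-coding transcript in the GENCODE annotation, and the fitted trend entered the model as an offset. A GC value was found for 16080 of the 16222 genes (99.12%). The counts, camera tests of lists and named genes were all computed again with this offset. Fry was not, so the GC trend can enter its calls in the LPS_ABS comparisons.

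Alternatives planned before the data were examined were size factors by relative log expression, total counts only, DESeq2 1.42.0, limma-voom, no filter and filters of 10 and 50 counts in 3 libraries. Others were fits of only the groups compared, a replicate block, log2(FPKM + 1) with and without a minimum of 1 FPKM in 3 libraries, log2(FPKM + 0.1) with that minimum, a threshold of 0.01 and the omission of each library.

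The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed per run. Of genes changed 1.5-fold, 2-fold and 4-fold, the fit recovered 13.7%, 72.2% and 91.8% for LPS against control. It recovered 15.5%, 67.2% and 92.7% for LPS_ABS against LPS, and 22.7%, 65.1% and 92.1% for LPS_ABS against control. With 5 runs each, false calls averaged 6.2, 5.2 and 7.8 in these comparisons. A simulated GC trend was then added to the LPS_ABS libraries. False calls for LPS_ABS against LPS averaged 1828 without the correction and 6.0 with it, and for LPS_ABS against control 1900.2 and 7.4. That trend was linear, alike in the 3 LPS_ABS libraries and built from the GC values that the correction fits. Its removal was therefore to be foreseen. The real slopes differed between the LPS_ABS libraries (0.22 to 0.36), so this does not measure how well the correction removes the real trend. Simulated lists raised 1.5-fold were found in 10 of 10 runs in each comparison, and 1, 0 and 0 of 230 other lists were called. Each simulated gene was drawn independently, so the few other lists called were to be foreseen. They do not measure false calls of lists whose genes vary together.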

Results

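Gene expression was measured by RNA sequencing in 9 libraries of PMA-treated THP-1 cells, 3 each from cells given PBS (control), LPS, and LPS with ABS (LPS_ABS). The series title concerns apoptotic bodies and macrophage polarization, so the comparisons ask what LPS changed and what changed further with ABS. Total counts per library were 39791729 to 41608801 in controls, 39168526 to 41679412 with LPS and 38506162 to 38893597 with LPS_ABS. Pearson correlations within groups lay between 0.972 and 0.990. The lowest joined LPS_ABS 1 and LPS_ABS 3, while LPS_ABS 1 stood at 0.967, 0.978 and 0.976 with LPS 1, 2 and 3.

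The LPS_ABS libraries differed from the others in how counts followed the GC content of the transcripts. The slope of log2 counts on GC content, per 10 GC points and relative to the mean of all libraries, was 0.30 ± 0.07 (SD, n = 3) with LPS_ABS, -0.15 ± 0.02 in controls and -0.15 ± 0.14 with LPS. In the lowest of 5 equal bins of genes by GC content, 7 were higher and 1394 lower in LPS_ABS than in LPS, and in the highest bin 995 were higher and 18 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Spearman's rho of log2 fold change with GC content across genes, which are not independent replicates, was 0.693 for LPS_ABS against LPS, 0.688 for LPS_ABS against control and 0.011 for LPS against control. Results after a GC correction are therefore given beside those 2 comparisons. Of 109 and 120 named values in them (LPS and control as reference), 45 and 36 kept their sign but lost their call with it. A further 5 and 3 called values changed sign and lost their call too. Genes named below as changed in them kept their call unless the text says otherwise. The LPS_ABS 3 library also stood apart in its share of ribosomal protein counts, 7.45% against 8.70 to 10.7% in the others. On the second principal component (30.3% of variance) it lay at 22.7, on the side of the controls (29.6 to 41.5), while LPS_ABS 1 and 2 lay at -16.7 and -14.01 and the LPS libraries at -30.8 to -34.4.

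**Figure D1:**
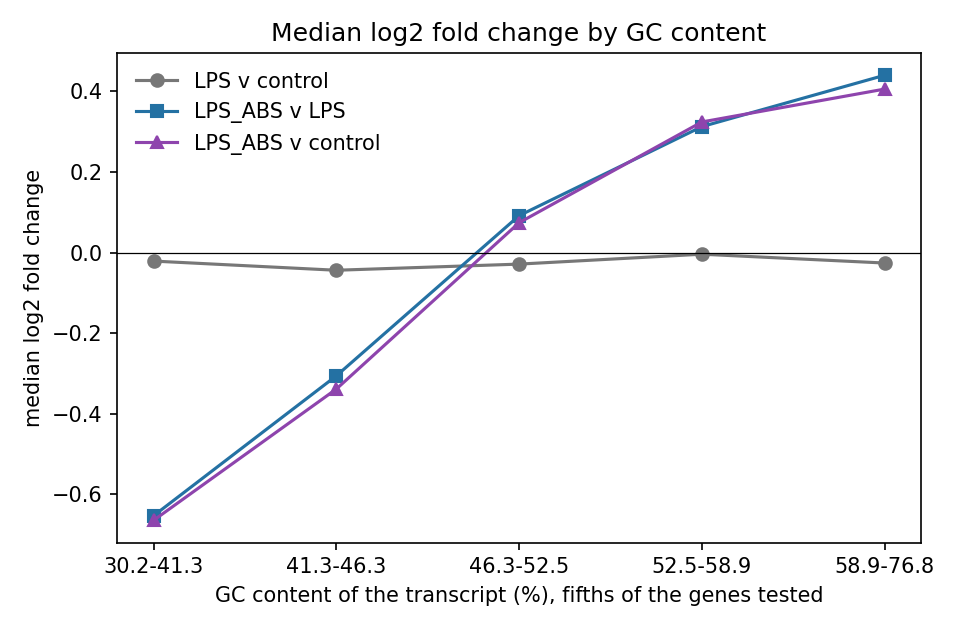
Median log2 fold change of genes (vertical axis) in 5 bins of transcript GC content in percent (horizontal axis), 1 line per comparison. For LPS_ABS against LPS the medians run from -0.65 in the lowest bin to 0.44 in the highest, and for LPS against control they stay between -0.04 and 0.00.

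With LPS 29 of 30 type I interferon response genes, the antiviral programme of the cell, and 11 of 20 stress response genes rose (6 fell), and 15 of 24 cholesterol synthesis and 11 of 23 glycolysis genes fell. None of these 4 lists was called with an estimated correlation (camera adjusted p = 0.259 each). IFI27 (gene ID 3429), an interferon-induced mitochondrial protein, rose from 90.9 ± 11.1 to 459.1 ± 115 CPM (SD, n = 3 each; log2 fold change 2.34 ± 0.21 SE, edgeR adjusted p = 7.9e-05). CHAC1 (gene ID 79094), a glutathione-degrading enzyme of the stress response, rose from 10.4 ± 3.67 to 135.1 ± 30.5 CPM (3.70 ± 0.31, adjusted p = 7.2e-05). IL1B (gene ID 3553), an inflammatory cytokine, fell from 42.0 ± 7.65 to 12.6 ± 1.002 CPM (-1.73 ± 0.20, adjusted p = 2.3e-04). TNF was not called, at 67.9 ± 30.6 CPM with LPS and 45.8 ± 3.29 CPM in controls (edgeR adjusted p = 0.393). Inflammatory cytokines were not called as a list with LPS and IL1B fell, which is unusual for LPS; the labels give no dose or time, and whether the time point or a wrong label accounts for it was not tested.

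In all, edgeR called 1933 of 12970 genes (14.9%) between LPS and control, 1000 higher and 933 lower, of which 607 changed at least 2-fold. After the GC correction 2745 were called, and 1899 of the 1933 were kept. The count was 907, 891 and 890 without control 1, 2 or 3, and 873 without LPS 3. Groups did not overlap in 42.6% of genes, where chance gives 10%. The largest rises by the fixed rule included S100P, a calcium-binding protein (4.63), SLC6A9, a glycine transporter (4.35), KLHDC7B (4.41), ST6GALNAC3, a sialyltransferase (4.18), TM6SF1 (4.10) and SYTL1 (3.98). The largest falls included TBC1D30 (-3.89), NPTX1, a secreted pentraxin (-2.95), SDC1, a cell surface proteoglycan (-2.35), TERT, the catalytic subunit of telomerase (-2.18), and ADAMTS1, a secreted protease (-2.07). All 11 values are log2 fold changes with edgeR adjusted p under 0.05.

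Of 24 lists, camera called 10 for LPS against control. None of them held with an estimated correlation, where the lowest adjusted p was 0.259 (3 lists had an unadjusted p under 0.05). Fry called 7, and not MHC class I presentation (adjusted p = 0.0655), NRF2 (0.145) and oxidative phosphorylation (0.15). Of 30 interferon response genes tested, 29 rose (30 adjusted over the list alone; camera adjusted p = 4.9e-28, adjusted p = 0.259 with an estimated correlation). Among them were the antiviral GTPase MX1 (1.96), EPSTI1 (2.15) and the RNA-sensing synthetase OAS2 (1.44). Of 20 unfolded protein and integrated stress response genes, 11 rose and 6 fell, adjusted over the list alone also 11 and 6 (adjusted p = 0.00141, 0.259 with an estimated correlation). The risers included the transcription factors ATF4 (1.72) and ATF3 (2.14) and the stress sensor SESN2 (2.52). The 6 that fell were CRELD2, HSP90B1, MANF, PDIA4, PDIA6 and SDF2L1, which act in protein folding in the endoplasmic reticulum.

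Of 24 cholesterol synthesis genes 15 fell with LPS (18 adjusted over the list alone; camera adjusted p = 2.7e-09, adjusted p = 0.259 with an estimated correlation), among them ACAT2 (-0.74), MVD (-0.88), NSDHL (-0.62) and CYP51A1 (-0.62). Without control 1 or control 2 the count was 7 or 9. Of 23 glycolysis and glucose uptake genes 11 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 1.9e-05, adjusted p = 0.259 with an estimated correlation). LDHA, which makes lactate, fell from 1085 ± 6.37 to 526 ± 84.8 CPM, and hexokinase HK2 (-1.63), the glucose transporter SLC2A1 (-0.80) and the aldolase ALDOC (-1.11) fell too. Without control 1 or 2, 6 or 5 glycolysis genes fell. Of 28 cell cycle genes 10 fell (11 adjusted over the list alone; adjusted p = 0.00141, adjusted p = 0.259 with an estimated correlation), with MCM4 (-0.88) and RRM2 (-0.89), both of DNA replication. That count was 3, 2 and 2 without control 1, 2 or 3, and 5 and 2 without LPS 2 or LPS 3.

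Lysosome genes were called up (9 of 28 rose, 9 adjusted over the list alone; camera adjusted p = 9.5e-05, adjusted p = 0.269 with an estimated correlation), including the hydrolase GLB1 (0.75) and the protease CTSB (0.58). Without control 1, 2 or 3, 3, 2 and 2 lysosome genes rose, and 2 without LPS 3. Of 17 MHC class I presentation genes 5 rose (8 adjusted over the list alone; adjusted p = 0.00326, adjusted p = 0.485 with an estimated correlation), among them HLA-E (1.07). That count was 3, 2 and 2 without control 1, 2 or 3, and 1 without LPS 3. Of 12 inflammasome and pyroptosis genes 3 rose (4 adjusted over the list alone; adjusted p = 0.0077, adjusted p = 0.259 with an estimated correlation), with the ATP receptor P2RX7 (2.23) and the thioredoxin-binding TXNIP (1.92). Of 18 NRF2 and oxidative stress genes 4 rose (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.0161, adjusted p = 0.643 with an estimated correlation), with malic enzyme ME1 (1.09). That list was not called without LPS 3 (adjusted p = 0.135), and its risers were 2, 1 and 1 without control 1, 2 or 3 and 2 without LPS 3. Of 35 oxidative phosphorylation genes 4 fell, none of them adjusted over the list alone (adjusted p = 0.0077, adjusted p = 0.654 with an estimated correlation), and the list was not called without LPS 2 (adjusted p = 0.21). EdgeR called 0 of its members without control 1, 2 or 3, LPS 2 or LPS 3; with all libraries 11 had an unadjusted p under 0.05 and limma-voom called 5.

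The other 14 lists were not called for LPS against control. Inflammatory cytokines and chemokines had 1 riser and 1 faller of 16 (2 and 3 adjusted over the list alone; camera adjusted p = 0.278), NF-kB feedback regulators 1 faller of 20 (0.389) and M1-type markers 1 of each of 18 (0.292). NF-kB feedback regulators were called down without LPS 3 (adjusted p = 0.0181). M2-type markers had 2 risers and 1 faller of 14 (0.292), with a median of 0.21 and a mean of -0.09. Anti-inflammatory mediators had 5 risers of 18 (5 and 1 faller adjusted over the list alone; 0.156), including TSC22D3, a glucocorticoid-induced regulator (2.29), and the transcription factor KLF2 (2.52). Toll-like receptor signalling components had 4 risers and 1 faller of 23 (0.593; median -0.06, mean 0.14), apoptotic cell uptake 2 and 2 of 24 (0.75), with the receptor AXL up (1.74), and LXR targets and cholesterol efflux 4 and 1 of 15 (0.278), with the exporter ABCA1 up (0.96). Without control 2, control 3 or LPS 3, 3 anti-inflammatory mediators rose, and without control 1, 2 or 3 the Toll-like receptor risers were 1, 0 and 1 and the LXR risers 1, 2 and 2. The Toll-like receptor risers were 2, 2 and 0 without LPS 1, 2 or 3, and the LXR risers 2 without LPS 2 or LPS 3. Apoptosis and p53 targets had 6 and 2 of 24 (0.143; 3 risers without LPS 3), with the secreted stress factor GDF15 up (3.04), matrix proteases 2 and 2 of 15 (0.947) and MHC class II 1 riser of 9 (0.156). Monocyte and macrophage identity had 3 and 1 of 24 (0.292; 5 risers without LPS 1), with the transcription factor CEBPB up (1.49), and immediate early genes 2 and 2 of 16 (0.278). Of 33 cytoplasmic ribosomal proteins edgeR called 0, 1 had an unadjusted p under 0.05, and limma-voom called 0 (list adjusted p = 0.947).

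**Figure D2:**
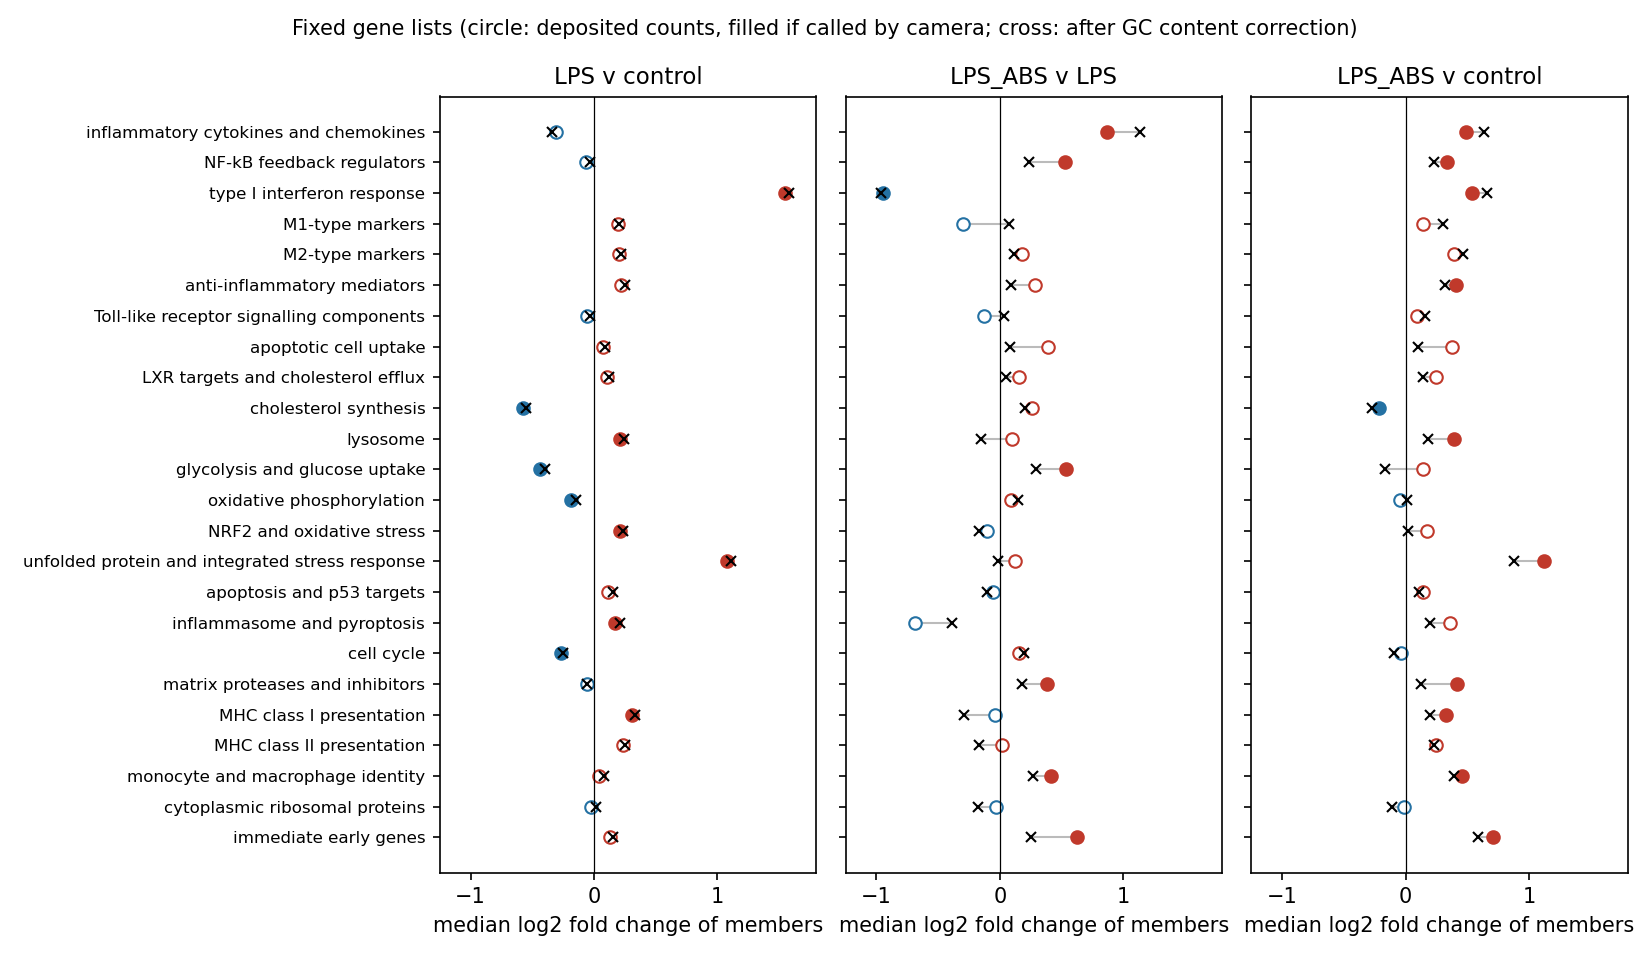
Median log2 fold change of the members of each fixed list (horizontal axis), 1 panel per comparison and 1 line per list. Circles are from the deposited counts, filled where camera called the list, and crosses are after the GC correction; the interferon list lies highest for LPS against control and lowest for LPS_ABS against LPS.

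With ABS added to LPS, 24 of 30 interferon response genes fell, and IL1B, 9 of 16 inflammatory cytokines and chemokines and 16 of 23 glycolysis genes rose. Of the glycolysis genes 5 rose after the GC correction, and no list was called with an estimated correlation (adjusted p = 0.323 to 0.989). IL1B (gene ID 3553) rose from 12.6 ± 1.002 CPM with LPS to 68.9 ± 17.4 CPM with LPS_ABS (SD, n = 3 each; log2 fold change 2.45 ± 0.20 SE, edgeR adjusted p = 3.1e-04), and by 2.61 after the GC correction. IFI44L (gene ID 10964), an interferon-induced gene, fell from 63.8 ± 20.002 to 12.4 ± 9.05 CPM (-2.37 ± 0.42, adjusted p = 0.00473), and by 1.79 after the correction. EdgeR called 4621 genes (35.6%), 2179 higher and 2442 lower, of which 837 changed at least 2-fold, but after the GC correction 1193 were called and only 773 of the 4621 (16.7%) were kept. The 3848 calls that ended had a median absolute log2 fold change of 0.67 before the correction and 0.25 after it, with a median SE of 0.18 and 0.15.

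Without LPS 1 or LPS 3, 2360 or 2720 genes were called between LPS_ABS and LPS, and without LPS_ABS 3 the corrected count was 727. Before the GC correction groups did not overlap in 46.2% of genes, where chance gives 10%, but the GC trend can part many genes at once. With total counts in place of TMM, 32.6% of called genes were higher, against 47.2%. The largest rises by the fixed rule were NPTX1 (3.19), SPRY4, an inhibitor of growth factor signalling (2.52), IL1B, PRRT4 (2.28), THBS1, thrombospondin (2.005), ADAMTS15 (1.98), EGR1, an immediate early transcription factor (1.96), and WNK2 (1.86). The largest falls included NEB, the muscle protein nebulin (-3.04), LRRC2 (-2.85), TMCC3 (-2.30) and COL24A1, a collagen chain (-2.17). VAMP7 (-3.41) and GOLGA8K (-2.18) lie in families or regions with near-identical copies, so their reads may be shared, and the VAMP7 call ended with the GC correction (adjusted p = 0.085) and without LPS 1 (0.126), LPS_ABS 2 (0.0804) or LPS_ABS 3 (0.0583).

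Of 24 lists, camera called 7 for LPS_ABS against LPS, and 14 after the GC correction, 6 of them among the 7. With an estimated correlation camera called none, the lowest adjusted p being 0.323 (3 lists had an unadjusted p under 0.05, and fry called 8). Fry, run only without the GC correction, called inflammasome genes down (adjusted p = 0.0483) and cell cycle up (0.0343), and not NF-kB feedback regulators (0.113). Interferon response genes fell in 24 of 30 (27 adjusted over the list alone; camera adjusted p = 3.1e-11, adjusted p = 0.699 with an estimated correlation), and in 24 after the correction (adjusted p = 8.2e-20). RSAD2 (-2.07) and EPSTI1 (-1.31), both antiviral, were among those that fell. Of 16 inflammatory cytokines and chemokines 9 rose (11 adjusted over the list alone; adjusted p = 8.3e-04, adjusted p = 0.716 with an estimated correlation), and 8 after the correction (adjusted p = 7.2e-07). They included the chemokine CXCL1 (1.34) and IL23A, an interleukin subunit (1.30). Without LPS 1, LPS 2 or LPS_ABS 1, 3, 5 and 5 cytokines rose. CXCL8 was not called (0.77, adjusted p = 0.0607) but was after the GC correction (1.54, adjusted p = 0.00144) and without LPS_ABS 3 (1.06, adjusted p = 0.0143). TNF was not called (0.25, edgeR adjusted p = 0.653), and neither was CCL2 (0.80, adjusted p = 0.0541; 1.28 after the correction, adjusted p = 0.0152), which was called without LPS 3 (0.0287) or LPS_ABS 3 (0.0199).

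Of 23 glycolysis and glucose uptake genes 16 rose with ABS (17 adjusted over the list alone; camera adjusted p = 1.1e-07, adjusted p = 0.323 with an estimated correlation), and 5 after the correction (adjusted p = 4.8e-05). HK2 rose from 7.85 ± 0.581 to 17.9 ± 5.05 CPM, SLC2A1 by 0.87 and GPI, which isomerises glucose phosphate, by 0.64, whereas the pyruvate kinase PKM (0.73) was not called after the correction (0.34, adjusted p = 0.0782). Of 24 monocyte and macrophage identity genes 9 rose (10 adjusted over the list alone; adjusted p = 1.7e-04, adjusted p = 0.323 with an estimated correlation), including the integrin ITGAM (1.16) and the calcium-binding S100A9 (1.27). This list was not called after the GC correction (4 rose and 1 fell, adjusted p = 0.0565), and 5 members rose without LPS 3. Of 16 immediate early genes 9 rose (9 adjusted over the list alone; adjusted p = 8.7e-04, adjusted p = 0.405 with an estimated correlation), with FOS (0.77), and 2 after the correction (adjusted p = 0.0271). Without LPS 1, 5 of them rose. Of 20 NF-kB feedback regulators 9 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00424, adjusted p = 0.716 with an estimated correlation), with the adaptor TRAF1 up (0.99), and after the correction 1 rose (adjusted p = 0.0271). Without LPS 1 or LPS 3, 5 or 14 of these rose. Of 15 matrix proteases and inhibitors 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0225, adjusted p = 0.323 with an estimated correlation), with MMP9, a gelatinase, up from 14.9 ± 3.27 to 49.1 ± 13.04 CPM. After the correction 2 matrix genes rose, and 3 did without LPS 1 or LPS_ABS 2.

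The other 17 lists were not called for LPS_ABS against LPS before the GC correction, and 8 of them were after it. Cholesterol synthesis had 10 risers and 4 fallers (camera adjusted p = 0.066; 4 risers after the correction, 0.00376), cell cycle 12 and 4 (0.135; 6 and 1, 0.002) and oxidative phosphorylation 6 and 3 (0.374; 6 risers, 0.00679), the 3 of them up after the correction. Cholesterol synthesis was also called up without LPS 1 (0.0278), LPS 3 (0.0291) or LPS_ABS 2 (0.0299), and cell cycle without LPS 1 (0.0112). Down after the correction were lysosome (0.0446), MHC class I presentation (0.0271), NRF2 and oxidative stress (0.0371), inflammasome and pyroptosis (0.0307) and ribosomal proteins (0.0237), with 1, 5, 1, 2 and 2 fallers. With an estimated correlation none of the 14 lists called after the correction was called (lowest adjusted p = 0.328). With the replicate block beside the correction lysosome was not called (0.0545), and monocyte and macrophage identity was (0.0359). Before the correction the 5 lists called down after it had 3 risers and 4 fallers (0.936), 2 and 1 (0.936), 5 fallers (0.245), 3 and 6 (0.245) and 3 fallers (0.456). Not called either way were M1-type markers (1 riser, 0.871), M2-type markers (2 and 1, 0.694), Toll-like receptor components (6 and 6, 0.92), apoptotic cell uptake (6 and 4, 0.182), LXR targets (1 riser, 0.517), the stress response list (5 and 2, 0.777), apoptosis and p53 targets (6 fallers, 0.469) and MHC class II (1 faller, 0.983). Anti-inflammatory mediators (4 and 1, 0.182) were called up without LPS_ABS 3 (0.047), and oxidative phosphorylation without LPS 1 (0.0421) or LPS_ABS 3 (0.047). Adjusted over the list alone, counts differed for cholesterol synthesis (13 and 5), cell cycle (12 and 6), oxidative phosphorylation (5 and 1), lysosome (1 and 4), MHC class I (1 and 1), M2-type markers (3 and 3), anti-inflammatory mediators (4 risers), Toll-like receptor components (8 and 6), apoptosis (4 fallers), LXR targets (no riser) and ribosomal proteins (1 faller). Member counts after the correction were 1 and 0 for anti-inflammatory mediators, 4 and 2 for apoptotic cell uptake, 2 and 1 for the stress response list, 1 faller for apoptosis and 1 for LXR targets, and 1 and 1 for M2-type markers, while edgeR called no Toll-like receptor or MHC class II member. Median and mean differed in sign for lysosome (0.10 and -0.02) and MHC class II (0.02 and -0.02).

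Against LPS, too, counts in the lists not called moved with single libraries. Toll-like receptor components had 3 risers and 3 fallers without LPS 1, and 3 fallers without LPS 3, LPS_ABS 2 or LPS_ABS 3. Apoptosis and p53 targets had 2 fallers without LPS 3, 3 without LPS_ABS 2, and 3 risers without LPS_ABS 3. NRF2 genes had 2 fallers without LPS 3, and 3 without LPS 1, LPS_ABS 2 or LPS_ABS 3. Without LPS 1, LPS 3 or LPS_ABS 2, edgeR called 1, 0 and 1 cholesterol synthesis genes down (18 of 24 had an unadjusted p under 0.05 with all libraries, and limma-voom called 16) and 1, 0 and 1 lysosome genes up (10 of 28, and limma-voom 7), with 1 of the latter up without LPS_ABS 3. Cell cycle had 1 faller without LPS 1 or LPS_ABS 2 and 7 without LPS_ABS 1, and apoptotic cell uptake 2 without LPS 1 or LPS 3. Oxidative phosphorylation had 1 faller without LPS 1, LPS 3 or LPS_ABS 3, and 10 risers without LPS_ABS 3. Inflammasome genes had 1 riser without LPS 1, 2 or 3 or LPS_ABS 2, the stress response list 3 without LPS 1 or LPS 3, and ribosomal proteins 1 faller without LPS 1 or LPS_ABS 1.

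**Figure D3:**
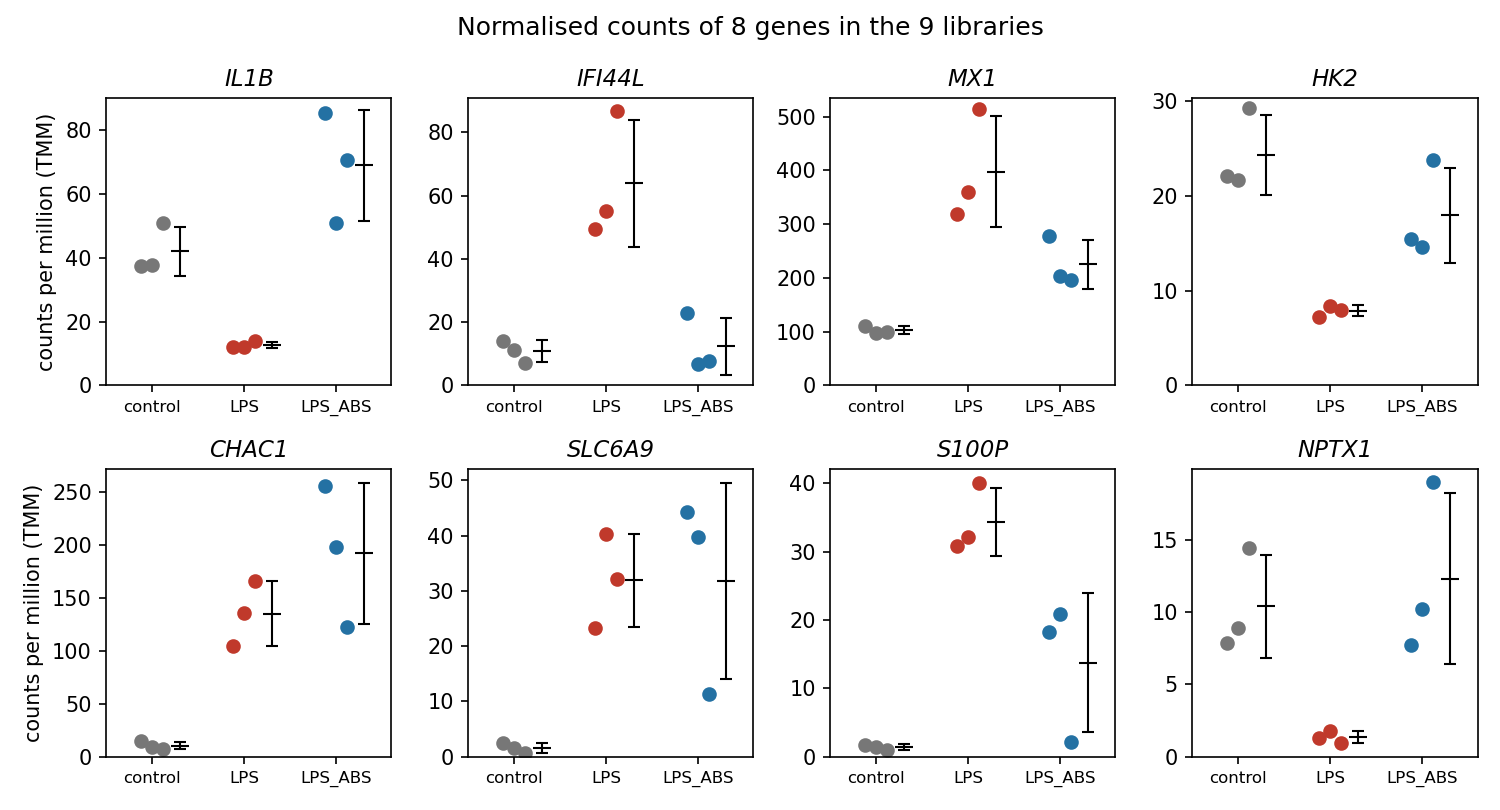
CPM of 8 genes (vertical axes) in the 3 groups (horizontal axes), with 1 point per library and the mean and SD over 3 libraries. IL1B is lowest with LPS (12.6) and highest with LPS_ABS (68.9), and CHAC1 is lowest in controls (10.4).

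Compared with control, 11 of 20 stress response genes, 15 of 30 interferon response genes and 12 of 16 immediate early genes rose with LPS_ABS, and 11 of 24 cholesterol synthesis genes fell. Of the immediate early genes 6 rose after the GC correction, the interferon list was not called without LPS_ABS 1 (camera adjusted p = 0.173), and no list was called with an estimated correlation (lowest adjusted p = 0.202). CHAC1 (gene ID 79094) rose from 10.4 ± 3.67 to 192.1 ± 66.8 CPM (SD, n = 3 each; log2 fold change 4.21 ± 0.32 SE, edgeR adjusted p = 3.9e-05) and by 3.80 after the GC correction. HMGCS1 (gene ID 3157), an early enzyme of cholesterol synthesis, fell from 321.8 ± 47.6 to 109.4 ± 38.7 CPM (-1.56 ± 0.21, adjusted p = 6.7e-04) and by 0.97 after the correction. IL1B was higher than in controls (0.72, adjusted p = 0.0137; 0.92 after the correction), but not called without control 1 (0.0646) or control 2 (0.062). EdgeR called 4388 genes (33.8%), 1920 higher and 2468 lower, of which 986 changed at least 2-fold. After the GC correction 1685 were called, and 1107 of the 4388 (25.2%) were kept.

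The 3281 calls between LPS_ABS and control that ended with the correction had a median absolute log2 fold change of 0.67 before it and 0.23 after it, with a median SE of 0.17 and 0.14. Without control 1 or control 2, 2351 or 2610 genes were called, and without LPS_ABS 3 the corrected count was 2609. Before the GC correction groups did not overlap in 49.97% of genes, where chance gives 10%, but here too the GC trend can part many genes at once. With total counts in place of TMM, 26.7% of called genes were higher, against 43.8%. The largest rises were SLC6A9 (4.34), NLRP12, a regulator of inflammation (4.29), CHAC1, SPTB, a spectrin (4.19), ADM2, a peptide hormone (4.05), INHBE (3.80), CTH, which makes cysteine (3.69), and SCN4A (3.64). Falls included TBC1D30 (-3.36), ZNF823 (-2.28), KIF21A, a kinesin (-1.88), VCPKMT (-1.84) and ATR, a DNA damage kinase (-1.75). U2AF1L5 (-1.84), a near-identical copy of another gene, was not called after the correction (adjusted p = 0.097), nor without control 2 (0.168), control 3 (0.0891), LPS_ABS 1 (0.088), LPS_ABS 2 (0.121) or LPS_ABS 3 (0.0901).

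Of 24 lists, camera called 11 for LPS_ABS against control and 10 after the GC correction, 9 of them among the 11. With an estimated correlation camera called none before or after the correction, the lowest adjusted p being 0.202 and 0.151 (4 lists had an unadjusted p under 0.05, and fry called 10). Fry called the M2-type (adjusted p = 0.0359), apoptotic cell uptake (0.0447) and LXR lists (0.0418) up, and not those of cytokines (0.115), NF-kB feedback (0.221), interferon response (0.221) and MHC class I (0.0634). It was run only without the GC correction, so the GC trend can enter these calls. Of 20 stress response genes 11 rose and 4 fell, adjusted over the list alone also 11 and 4 (camera adjusted p = 0.00403, adjusted p = 0.202 with an estimated correlation), after the correction 11 and 3, with SESN2 (3.22), ATF4 (1.47) and XBP1 (1.61). The 4 fallers were 2 without control 1, 2 or 3 or LPS_ABS 2. Of 30 interferon response genes 15 rose (16 adjusted over the list alone; adjusted p = 0.00403, adjusted p = 0.689 with an estimated correlation), and 12 after the correction, with IFI27 (1.65), MX1 (1.14) and STAT2 (1.07). Without LPS_ABS 1 the interferon list was not called (adjusted p = 0.173), and 5 of its members fell. Cytokines and chemokines were called up with 3 risers of 16 (3 adjusted over the list alone; adjusted p = 0.0133, adjusted p = 0.604 with an estimated correlation), including CCL2 (1.44) and IL23A (2.47). They had 6 risers after the correction and 7 without LPS_ABS 3, and were not called without LPS_ABS 1 (adjusted p = 0.114). TNF (0.82, edgeR adjusted p = 0.134) was called without LPS_ABS 3 (1.21, 0.00873). NF-kB feedback regulators had 7 risers and 1 faller of 20 (7 and 1 adjusted over the list alone; adjusted p = 0.0384, adjusted p = 0.689 with an estimated correlation), and were not called after the correction (0.312) or without LPS_ABS 1 (0.173). Of them 3 and 4 rose without control 1 or 2, and 4 and 3 without LPS_ABS 1 or 2.

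Of 24 identity genes 16 rose against control (16 adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.202 with an estimated correlation), 8 after the correction, among them the LPS co-receptor CD14, from 17.5 ± 1.02 to 55.1 ± 16.2 CPM, and CEBPB (1.81). That count was 7, 7 and 8 without control 1, 2 or 3, and 10 without LPS_ABS 1 or 2. Of 16 immediate early genes 12 rose (13 adjusted over the list alone; adjusted p = 1.2e-05, adjusted p = 0.202 with an estimated correlation), 6 after the correction, with EGR1 (1.60), ATF3 (1.99) and ZFP36, which destabilises cytokine mRNA (0.83). Without LPS_ABS 2, 7 of them rose. Of 18 anti-inflammatory mediators 6 rose (6 adjusted over the list alone; adjusted p = 0.00403, adjusted p = 0.52 with an estimated correlation), 5 after the correction, with TSC22D3 (2.05) and KLF2 (2.47). Of 28 lysosome genes 14 rose and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 0.00654, adjusted p = 0.52 with an estimated correlation), 7 rose after the correction, with GLB1 (0.75) and CTSB (0.62). Without control 1, 2 or 3, 6, 7 and 8 lysosome genes rose, and 1 fell without control 1, control 2 or LPS_ABS 2. Matrix proteases had 8 risers and 2 fallers (9 and 2 adjusted over the list alone; adjusted p = 0.0166, adjusted p = 0.202 with an estimated correlation), with MMP9 up (1.34), and 4 risers after the correction or without control 1, 2 or 3 or LPS_ABS 2.

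Cholesterol synthesis had 11 fallers and 1 riser of 24 against control (11 and 1 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.604 with an estimated correlation), and 10 fallers after the correction (adjusted p = 7.9e-06), with IDI1 (-1.23). Without control 1 or LPS_ABS 2, 7 fell. MHC class I presentation had 7 risers (7 adjusted over the list alone; adjusted p = 0.021, adjusted p = 0.604 with an estimated correlation) and 1 after the correction, when it was not called (0.198), nor was it without LPS_ABS 1 (0.101), and 4 rose without control 2 or 3. Ribosomal proteins were called down after the correction only (7 fallers before it, adjusted p = 0.375, and 3 after it, adjusted p = 0.0299). Not called were glycolysis (4 risers and 3 fallers, 0.247), oxidative phosphorylation (2 and 9, 0.375), cell cycle (6 and 8, 0.601), inflammasome genes (6 and 2, 0.268), apoptotic cell uptake (7 and 2, 0.0626), LXR targets (3 and 1, 0.115), M1-type markers (3 and 1, 0.651), M2-type markers (3 and 1, 0.191), Toll-like receptor components (3 and 4, 0.868), MHC class II (1 and 1, 0.33), NRF2 genes (5 and 2, 0.505) and apoptosis and p53 targets (5 and 6, 0.651). With total counts in place of TMM apoptotic cell uptake was called up (0.0497). Adjusted over the list alone, counts differed for M1-type markers (2 and 1), oxidative phosphorylation (1 and 7), NRF2 (5 and 3), apoptosis (7 and 7), cell cycle (8 and 10) and ribosomal proteins (3 fallers). After the correction the lists not called before it, ribosomal proteins apart, were still not called, with glycolysis at 3 and 4 (median 0.15 before and -0.17 after), oxidative phosphorylation 4 and 3, cell cycle 3 fallers, inflammasome 3 risers, apoptotic cell uptake 1 and 1, NRF2 3 and 1, apoptosis 6 risers, M1-type markers 4 and 1, Toll-like receptor components 3 and 1, LXR targets 3 risers and no MHC class II member called.

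Many of these counts against control moved when 1 library was left out, which also leaves fewer libraries in the fit. Without control 1, 2 or 3, edgeR called 0, 1 and 0 NRF2 genes up (9 of 18 had an unadjusted p under 0.05 with all libraries, and limma-voom called 7), and 2 and 1 without LPS_ABS 1 or 2. Apoptosis and p53 targets had 2 fallers without control 1, 2 or 3 or LPS_ABS 2, 3 risers without control 1 and 8 without LPS_ABS 3. Apoptotic cell uptake had 3, 1 and 4 risers without control 1, 2 or 3, and 2 and 4 without LPS_ABS 2 or 3. Inflammasome genes had 3 risers without control 1, control 2 or LPS_ABS 2. Oxidative phosphorylation had 4, 5 and 4 fallers without control 1, 2 or 3, and 4 risers without LPS_ABS 3. Ribosomal proteins had 3 fallers without control 1, 2 or 3, 4 without LPS_ABS 1 or 3, and 5 risers without LPS_ABS 3. Cell cycle had 5 fallers without control 1 and 3 risers without control 1 or 3, and glycolysis 1 faller without control 1, control 2 or LPS_ABS 2. Toll-like receptor components had 1 riser without control 1, control 2 or LPS_ABS 2, 5 without LPS_ABS 3, and 7 fallers without LPS_ABS 1. LXR targets had 5 risers without LPS_ABS 3, and M1-type markers 4 fallers without LPS_ABS 1.

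Of the 18 landmark genes 14 could be tested. HMOX1, a haem-degrading enzyme, was higher than control with LPS (0.85, edgeR adjusted p = 0.0225) and LPS_ABS (0.81, adjusted p = 0.0153). With LPS that call ended without control 1, 2 or 3 (0.0807, 0.0503 and 0.0934) or LPS 3 (0.118), and with LPS_ABS without control 1 or 3 (0.0578 and 0.0567) and after the GC correction (0.45, 0.134). ABCA1 was higher than control in both (0.96 and 0.86). TGFB1, a regulatory cytokine, was higher in LPS_ABS than in LPS (0.66, adjusted p = 0.00722), but not after the correction (0.22, 0.18). MERTK, a receptor for apoptotic cells, was higher in LPS_ABS than in LPS (1.05, adjusted p = 0.0409) and control (1.09, 0.0367). Neither MERTK call held after the correction (0.0765 and 0.0532), and against LPS it ended without LPS 1 (0.0735), LPS 3 (0.133), LPS_ABS 2 (0.0811) or LPS_ABS 3 (0.11). Against control it ended without control 2 (0.132), control 3 (0.0776), LPS_ABS 2 (0.0778) or LPS_ABS 3 (0.0909). CXCL10, NFKBIA, PTGS2, IDO1, CD80 and CD163 were called in no comparison of all 9 libraries. NFKBIA was called up by edgeR against LPS without LPS 3 (0.72, adjusted p = 0.023) or LPS_ABS 3 (0.57, 0.0468), and against control without LPS_ABS 3 (0.61, 0.03). Without LPS_ABS 1, CXCL10 was called down against control (-1.03, adjusted p = 0.0279), and CD80 against LPS (-3.03, 0.0223) and control (-3.18, 0.0191). CD80 lay under 1 CPM in all 9 libraries, with 0.54, 0.13 and 0 CPM in LPS_ABS 1, 2 and 3. CXCL8 was not called against control (0.45, adjusted p = 0.255), but was after the correction (1.16, 0.00161) and without LPS_ABS 3 (0.0372).

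Markers of cell types other than THP-1 were low apart from single genes. Summed CPM in control, LPS and LPS_ABS was 11.997, 11.7 and 14.6 for fibroblast markers, 9.52, 10.001 and 11.5 for T cell markers, 11.4, 16.6 and 15.9 for B cell markers and 67.5, 74.6 and 78.2 for endothelial markers, where EGFL7 held 97.6%. Chondrocyte markers summed to 1543, 1497 and 1831 CPM, of which COL9A2 alone held 99.9%. Epithelial markers summed to 5.24 ± 0.950, 21.2 ± 1.40 and 13.9 ± 3.93 CPM (SD, n = 3), and CLDN7, a tight junction protein, rose with LPS (2.79) and with LPS_ABS against control (2.14). COL1A1, a fibroblast collagen at under 1 CPM, fell with LPS (-2.31, edgeR adjusted p = 0.0392), a call that ended without each of the 6 libraries (adjusted p = 0.0757 to 0.139), and rose with LPS_ABS against LPS (2.73, adjusted p = 0.011).

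The LPS_ABS libraries differed among themselves in how much of the LPS change they showed, a check added after the results were seen. Over the 1933 genes changed by LPS, the slope of each library's log2 change from the control mean on that of the LPS mean was 0.71, 0.73 and 0.31 for LPS_ABS 1, 2 and 3, and 0.70, 0.72 and 0.30 after the GC correction. Of these genes 742, 724 and 1221 lay nearer the control mean than the LPS mean. S100P stood at 18.3, 20.8 and 2.15 CPM and ST6GALNAC3 at 15.25, 11.1 and 1.20 CPM in the 3 libraries. The cause is open, since the labels give nothing that sets LPS_ABS 3 apart. The LPS_ABS means in all comparisons therefore join unlike libraries.

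Of the 1933 genes changed by LPS, 787 (40.7%) moved the opposite way in LPS_ABS against LPS, 293 that LPS raised and 494 that it lowered, while 67 moved further the same way. Both comparisons use the LPS libraries, and unchanged groups simulated 50 times with the same sharing gave 0 such genes in every run. Few genes are called where nothing changed, so this 0 was to be foreseen and does not measure the part of the shared libraries; independent lists of these sizes would share 345. The covariance of the log2 fold changes was -0.177, against -0.042 in the simulations, a difference of -0.136, and Pearson's r was -0.43 against -0.50. After the GC correction 591 of 2745 moved back and 8 moved further. Without control 1, 2 or 3 the count was 385, 363 and 370 (42.4%, 40.7% and 41.6% of the genes then changed by LPS). Without LPS 1 or LPS 3 it was 439 or 313 (25.9% or 35.9%). Without LPS_ABS 3, the library nearest the controls, it was 811 of 2710, a lower share (29.9%). With the LPS libraries parted 1 and 2, so that the comparisons shared none, the covariance was -0.087 to -0.196 over the 6 partings (mean -0.138). This check was added after the results were seen. EdgeR then called 0 to 372 genes as moved back and 0 to 192 as moved further. It called 318 back and 192 further with LPS 1 alone compared with LPS_ABS, 138 and 39 with LPS 2 alone compared with control, and 0 back where LPS 2 alone was compared with LPS_ABS (891 moved back at an unadjusted p under 0.05 in both comparisons; no other tool was run). The low share that moved further, 67 beside 787, therefore did not hold in every parting. A lone library was taken to vary like the other groups, and part of the count of 787 may come from the shared libraries.

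Of the same 1933 genes, 921 (47.6%) changed in the same direction in LPS_ABS against control, 621 up and 300 down, and 18 changed the opposite way. Independent lists would share 326, and simulated unchanged groups gave 0, which says as little here. The covariance was 0.243, against 0.042 in the simulations, a difference of 0.201, and Pearson's r was 0.55 against 0.50. After the GC correction 920 of 2745 changed the same way. The count was 413, 435 and 447 without control 1, 2 or 3 (45.5%, 48.8% and 50.2% of the genes then changed by LPS). It was 464 without LPS 3 (53.2%) and 1478 of 2710 without LPS_ABS 3 (54.5%). With the controls parted 1 and 2 in the same way, the covariance was 0.197 to 0.251 (mean 0.221), and 96 to 219 genes changed the same way, so part of the count of 921 may come from the shared controls.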

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

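The GC settings were chosen after seeing the data; the others were planned, and all of them were run. Fitting only the groups compared called 3245 genes for LPS against control and 3042 for LPS_ABS against LPS. An adjusted p under 0.01 left 702, 1516 and 1903 genes (LPS against control, LPS_ABS against LPS, LPS_ABS against control). The GC correction called 1193 and 1685 genes in the LPS_ABS comparisons against LPS and control, 1409 and 1754 with the replicate block as well, and 727 and 2609 without LPS_ABS 3. Leaving out 1 library of the groups compared gave 873 to 1698, 2360 to 4918 and 2351 to 4679 genes, with fewer libraries in the fit. All groups share 1 estimate of the spread, and without LPS_ABS 1, 2 or 3 the LPS against control count was 2562, 1906 and 2710. Leaving out any 1 library gave 313 to 1043 genes moved back with ABS and 413 to 1478 changed alike with and without ABS. For LPS_ABS against control 7 to 11 lists were called without 1 library of these groups. With an estimated correlation camera called 0 lists in each comparison (3, 3 and 4 at an unadjusted p under 0.05; fry called 7, 8 and 10). After the GC correction 14 lists were called for LPS_ABS against LPS, and 14 with the block too, where lysosome (0.0545) was lost and monocyte and macrophage identity (0.0359) gained. Relative log expression, total counts, DESeq2, limma-voom, the count filters and the FPKM settings kept the number of genes called in each comparison within 1.5 times, but not each direction: genes higher in LPS_ABS than in control fell from 1920 to 1192 (total counts), 1167 and 1158 (FPKM + 1 and + 0.1, filtered) and 953 (FPKM + 1, no filter), and those higher than in LPS from 2179 to 1140 (FPKM + 1, no filter).

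Among named genes, 8 called values changed sign with the GC correction, and none of them was called after it. Against LPS these were LAMP2 (0.0474), GCLM (0.13), B2M (0.10), RPL7 (0.0906) and RPS6 (0.10), and against control LAMP2 (0.15), TXN (0.0087) and CTSS (0.20). Of the 337 values of named genes recomputed with this correction, 81 more lost their call with the same sign and 3 gained it. Under the other planned settings 47 lost and 7 gained their call of 2588, and with 1 library left out 262 and 11 of 2022. No called value changed sign in either. The cause was not tested beyond the GC trend that the correction removes.

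No label says that the replicate numbers pair the samples, and the counts leave open whether some do. Residual correlations of same-numbered libraries ran from -0.035 to 0.203, with 3 of 9 above 0.1, against -0.204 to 0.172 for different numbers. The replicate block called 1960, 4838 and 4573 genes, against 1933, 4621 and 4388 without it. Depth was similar in all 9 libraries and limits mainly genes with few counts, such as IL6, IL10 and CD86.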

Other observations

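Chosen only after the results were seen were the Gene Ontology tests, the lists of ATF4 targets and of ER chaperones and their 2 tests, the tests of short-lived transcripts, of GC content on the interferon and cytokine genes and of the shared LPS libraries, and the gene neighbourhood.

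Gene Ontology terms of 15 to 200 genes (2026 terms, camera with a preset correlation) described further groups, none of which was called with an estimated correlation (lowest adjusted p = 0.926; 0.997 for LPS against control). For LPS against control, rRNA processing was lower (41 genes fell and 3 rose of 141, adjusted p = 1.4e-06), as were the small-subunit processome (15 fell and 1 rose of 38), DNA replication (27 and 3 of 125), mitochondrial translational elongation (18 fell of 88) and structural constituent of nuclear pore (9 fell of 23). Genes of the cellular response to copper ion, which hold metallothioneins, were higher (8 rose of 16). For LPS_ABS against control, rRNA processing was lower (43 fell and 7 rose; 24 and 5 after the GC correction), and amino acid transport (10 rose and 1 fell of 26; 10 rose after it) and ficolin-1-rich granule membrane (22 and 7 of 49; 12 and 2 after it) were higher. Terms called both with and without the GC correction numbered 58, 0 and 14 in the 3 comparisons (LPS against control, LPS_ABS against LPS, LPS_ABS against control).

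In the RefSeq gene order of assembly GRCh38.p14, 20 neighbouring genes from BMP8B to CTPS1 on chromosome 1 had the highest median level of 12508 such windows in controls, a log2 CPM of 8.79 against a median of 4.48 over all windows. CAP1, PPT1 and SMAP2 stood at 9992, 4058 and 2701 CPM there, and COL9A2, a cartilage collagen chain that held nearly all counts of the chondrocyte list, at 1542 CPM.

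The log2 fold changes of both LPS_ABS comparisons followed GC content. Among 142 subunits of 5 housekeeping complexes, which are usually made in fixed proportions, the slope for LPS_ABS against LPS was 79.9% of that over all genes (0.35 ± 0.03 against 0.44 log2 per 10 GC points), a value that bias between the libraries would give. Gene length bias is argued against as the whole cause, since the trend held within 5 bins of gene length, but it was steeper in longer genes (61.8%, 90.1%, 107%, 122% and 140% of the slope over all genes, median 107%). Loss of short-lived transcripts stays open: immediate early genes had a median of 0.63, but they are rich in GC (56.0%), and after the correction the median was 0.25 with 2 of 16 called up. An effect of ABS that follows GC content stays open too, since group and library preparation cannot be separated by the labels.

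The fall of interferon response genes and rise of cytokine genes in LPS_ABS against LPS is not accounted for by GC content, since 91.7% of the interferon members that fell (22 of 24, median -1.18 before and -1.01 after the correction) and 6 of 9 cytokines kept their call. Nor does a single library of the LPS or LPS_ABS group account for the interferon fall: without any 1 of these 6 libraries at least 17 members were called down. For the cytokines the test cannot decide, since it asked only that at least 1 member stay called. EdgeR called 3 cytokines up without LPS 1, against 9 with all libraries. Calls over all genes also fell without LPS 1, from 4621 to 2360. The drop therefore cannot tell whether that count rests on LPS 1 or on the size of the fit. Chance values of the shared LPS libraries stay open: the 29 interferon members raised by LPS had a median of 0.55 in LPS_ABS against control, between 0 and the lower quartile of 1.36 in LPS against control. That test's bounds were replaced after its value was seen, because the first bounds, under which the value counted against chance, would also be met by LPS libraries that were high by chance. An effect of ABS is a hypothesis here, untested on independent samples.

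All 28 ATF4 and amino acid starvation targets rose with LPS (median 2.59; camera adjusted p = 8.2e-35, adjusted p = 0.0439 with an estimated correlation). In LPS_ABS against control 28 rose too (median 2.24; adjusted p = 0.131 with an estimated correlation). These camera p-values were adjusted over the ATF4 and ER chaperone lists alone, so they cannot be compared with those of the fixed lists. With an estimated correlation the unadjusted camera p for LPS against control was 0.0288. The fixed stress response list had a lower one (0.0222) and an adjusted p of 0.259. The ER chaperone list had the same adjusted p as the targets there (0.0439). In LPS_ABS against LPS 2 rose and 1 fell (median -0.03), and after the GC correction edgeR called 0 up and 1 down (0 and 6 at an unadjusted p under 0.05; median -0.20, camera unadjusted p = 0.00472). GC content is argued against as the cause of the rise with LPS, since the medians of 5 bins of genes by GC content lay within 0.044 of 0 in that comparison. ER folding stress stays open: of 10 ER chaperone and folding genes 6 fell (median -0.56), but these 6 had prompted the test, and HERPUD1 (1.55) and XBP1 (1.45), both induced by such stress, rose. The targets were listed after their values were seen, so the share that rose and its p-values overstate the evidence, and an LPS effect on amino acid sensing is a hypothesis only.

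With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 1933, 4621 and 4388 genes, against 1, 0 and 0 in the highest other split, and was the only 1 of 10 with as many in each comparison. For lists it called 10, 7 and 11, against 10, 15 and 10 in the highest other split, with as many in 2, 6 and 1 of 10 splits. Of 100 drawn splits of the 9 samples, 1, the real one, gave as many genes moved back (787, highest other 686). Again 1, the real one, gave as many changed alike with and without ABS (921, highest other 366). Splits that mix treatments widen the spread within groups, so few genes are called in them and this outcome was to be foreseen. It therefore excludes neither a random grouping of the libraries nor a part played by the shared libraries. The split with 686 kept the LPS_ABS libraries together, a structure of the samples that the GC trend shares.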
